A study of Homo sapiens with 12 samples.

How the data were processed

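The libraries were made from SAS cells, a line derived from an oral squamous cell carcinoma. Per the labels, 8 libraries came from sorted fractions of SAS-Fucci cells, which carry fluorescent cell cycle reporters that let G1 cells be sorted from cells in S, G2 or M phase: G1 or S/G2/M, from unstimulated cells or from cells given TGF-β at 1 ng/ml for 72 h. Another 4 libraries came from unsorted clones, labelled as SAS cells without naming the reporters, that carried a control guide RNA (sgRNA) or an sgRNA against KRTAP2-3. Each of the 6 groups had 2 libraries, which the labels call biological duplicates. The labels do not say whether the 2 libraries of a clone group were 2 clones, and the p-values of single genes measure only the spread between these libraries. The main p-values of gene lists rest mainly on the spread across genes, as described below. Per the labels' protocols, polyadenylated RNA was selected and libraries were made with an Ion Total RNA-Seq kit. Per the submitters' processing notes, HISAT2 2.1.0 and StringTie 2.0.4 were used with the genome build GRCh38; the roles of the tools, the annotation and the strand setting are not given in the sources used here.

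The deposited files gave TPM, FPKM and mean coverage for each gene model, made by the authors and kept as deposited. TPM summed to 1000000 in each library, and the ratio of the deposited TPM to FPKM was a constant per library (1.84 to 2.18). The coverage values deposited by the authors were used only to describe depth. Each file held 33121 gene models with 30017 names; 3240 models lay on alternate or unplaced contigs and 1225 names had more than 1 model. TPM was summed per name. The 24 models on the mitochondrial chromosome included none of the 13 protein genes in the mitochondrially encoded list. Some symbols in the files are older ones (CTGF for CCN2, CYR61 for CCN1, IL8 for CXCL8), and coordinates are those of GRCh38 as in the files. The files hold no read counts, so the number of reads per library is unknown and no count model was used. As a relative measure of depth, the commonest ratio of coverage to FPKM (shared by 30.7 to 33.4% of expressed genes) was 1.04 to 1.24 in the replicate 1 libraries of the sorted fractions, 0.563 to 0.682 in their replicate 2 libraries and 0.500 to 0.707 in the clones. An exact 0 can be a failed estimate in such files: 197 genes were listed at 0 in 1 library of a pair and at 5 TPM or more in the other. Such genes are given as listed at 0, with the value of each library. Of all genes, 4448 overlapped another gene model on the same strand, and values of such genes and of near-identical copies are uncertain.

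Expression was tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Genes with at least 1 TPM in at least 2 libraries of the fit were kept, which left 13596 genes in the sorted fractions and 12993 in the clones. Folds are on the log2(TPM + 1) scale, which understates the change of low genes, and "rose" and "fell" are used only for genes past the threshold. The 8 sorted libraries shared 1 fit with a term per group (4 residual degrees of freedom, prior degrees of freedom 2.72), and the 4 clone libraries had their own fit (2 residual, 4.63 prior). The 6 contrasts were TGF-β in G1, TGF-β in S/G2/M, G1 against S/G2/M without and with TGF-β, the interaction of phase and TGF-β, and the KRTAP2-3 sgRNA clones against the control sgRNA clones.

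The design, the contrasts, the rule for named genes, 25 gene lists and most of the alternatives were fixed before the data were examined. The lists were TGF-β/SMAD targets, ID genes, mesenchymal markers and EMT transcription factors, epithelial adhesion and identity, epithelial keratins, squamous differentiation, keratin-associated proteins, collagens and extracellular matrix, integrins, invasion proteases and their regulators, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and D cyclins, p53 targets, interferon-stimulated genes, hypoxia and glycolysis, immediate early and heat shock genes (sorting stress), cytokines and chemokines, unfolded protein and amino acid stress response, cholesterol synthesis, YAP/TAZ targets, ribosomal proteins and mitochondrially encoded genes (RNA quality), and markers of fibroblasts and of blood and endothelium. Lists were tested with limma's camera (preset correlation 0.01), adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. Camera compares the genes of a list with all other genes at that assumed correlation. Its p-values therefore rest mainly on the spread across genes and can be very small with 2 libraries per group. The estimated correlation comes from few residual degrees of freedom and called no list in any contrast, not even G2/M genes between the unstimulated phases. A call lost with it therefore cannot tell a list that moved from one that did not. Named genes were the KRTAP2 genes, up to 4 called members of each list with at least 5 TPM and groups that did not overlap, the 8 largest called rises and falls per contrast, and a fixed set of markers given whatever their test. The values of 2 of the named genes are not reported here, and both genes stayed in every test and count. The genes that TGF-β moved in G1 were also tested as sets in the clones, which share no library with the sorted fractions.

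Samples that share a replicate number deviated together in the sorted fractions: the deviations from the group means correlated at 0.41 to 0.50 across genes in all 6 pairs of groups. The replicate number was therefore read as a batch. The labels do not say what it marks, so its source may be technical or biological. The number of genes called with the replicate as a block is given for each contrast of the sorted fractions and for most of the lists described. Reading the number as a batch was decided after the blocked counts had been seen. In the clones the correlation was 0.14. Other alternatives were the pseudocount, the filter, quantile normalization, trimmed-mean scaling, FPKM in place of TPM, eBayes without the trend, the libraries that set the spread, and leaving out each library; 4 more were added after the data had been seen.

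The fit was tested on simulated data in which 200 genes were changed by known amounts. The changed genes were drawn from those with a mean log2 value above that of 5 TPM, so recovery is not shown for lower genes. Noise was drawn separately for each gene and library. The false calls therefore hold for data without the deviations that libraries of a replicate number share. For TGF-β in G1 (13295 genes), 36 of 67 genes changed 2-fold were called, 55 of 67 changed 4-fold and 63 of 66 changed 8-fold, with 4 false calls among 158. For the clones (12705 genes), 13 of 67, 50 of 67 and 62 of 66 were called, with 7 false calls among 132. Tables were joined in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6; figures were drawn with matplotlib 3.10.9.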

Results

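RNA-seq libraries of SAS oral squamous carcinoma cells were compared in 6 groups of 2. In the sorted experiment, G1 and S/G2/M fractions of SAS-Fucci cells, which carry cell cycle reporters, came from unstimulated cells and from cells given TGF-β, a cytokine that can drive epithelial cells towards a mesenchymal state, at 1 ng/ml for 72 h. In the clone experiment, unsorted clones labelled as SAS cells carried a control sgRNA or an sgRNA against KRTAP2-3, a keratin-associated protein gene. Between 12600 and 12971 genes had at least 1 TPM in each library, and log2 values of replicate libraries correlated at 0.968 to 0.982 across genes, which are not independent replicates. The first principal components held 29.6%, 25.8% and 20.2% of the variance in the sorted libraries and 47.6%, 32.3% and 20.1% in the clones. In the clones these are all the components that 4 libraries have, so the shares of the experiments cannot be compared. The clone component with 32.3% set the control libraries apart from each other (−28.9 and 28.3). Read depth is unknown; gene models of small or mitochondrial RNA took 2.17 to 3.1% of TPM in replicate 1 of the sorted groups, 4.1 to 5.43% in replicate 2 and 1.73 to 2.36% in the clones.

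KRTAP2-3 (chromosome 17, 41059240 to 41060092, minus strand, GRCh38) was read first in every library. It stood at 91.5 and 94.7 TPM in unstimulated G1, 83.3 and 83.2 in unstimulated S/G2/M, 205 and 182 in TGF-β G1, and 101 and 112 in TGF-β S/G2/M. Unsorted control sgRNA clones had 20.4 and 19.2 TPM and KRTAP2-3 sgRNA clones 2.70 and 6.96 TPM, so both libraries labelled with the KRTAP2-3 sgRNA lay below both controls. That difference (log2 −1.94, SE 0.36) did not pass in limma (adjusted p = 0.0728), and an sgRNA need not lower the transcript. With every library kept, the adjusted p was 1.5e-04 with the replicate block and 0.242 with no filter on low values. It was 0.0410 with a filter of 5 TPM and 0.0132 with the spread of all 12 libraries. Leaving out a KRTAP2-3 sgRNA library keeps 1 in that group and drops the spread between its libraries, so no p-value is given for it. The copies next to it on chromosome 17, KRTAP2-1 (41046541 to 41047316), KRTAP2-2 (41054498 to 41055211) and KRTAP2-4 (41065116 to 41065879), share stretches of sequence with it, so their values are uncertain. The 4 genes summed to 113 ± 9.94 TPM (SD, n = 2) in unstimulated G1, 101 ± 4.32 in unstimulated S/G2/M, 248 ± 6.06 in TGF-β G1, 138 ± 18.1 in TGF-β S/G2/M, 23.9 ± 2.85 in control clones and 6.41 ± 3.23 in KRTAP2-3 sgRNA clones.

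**Figure D1:**
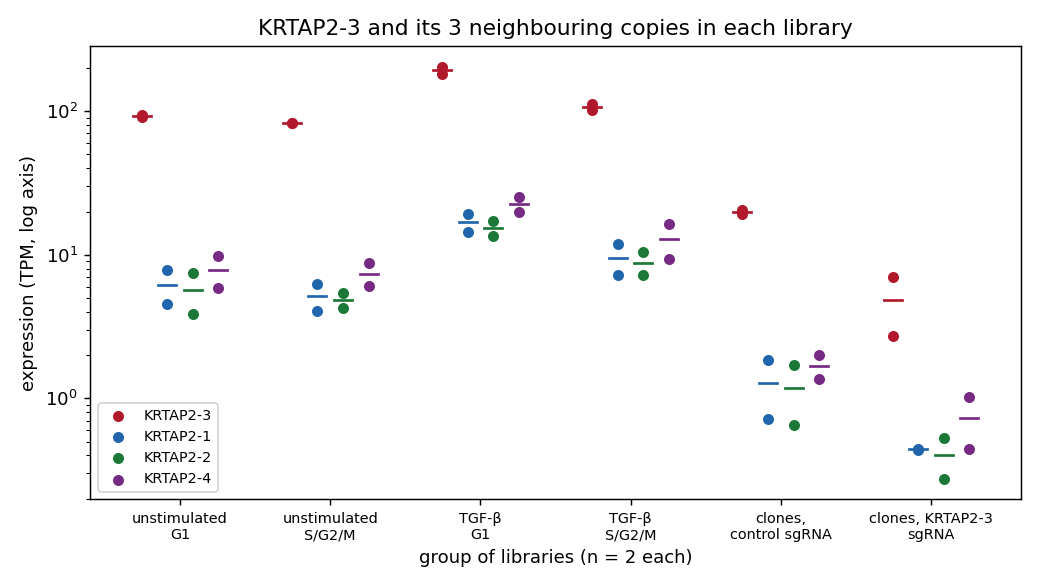
Expression (TPM, log axis) of KRTAP2-3 and the copies KRTAP2-1, KRTAP2-2 and KRTAP2-4 in each of the 12 libraries; points are libraries and short lines are means of 2 libraries. KRTAP2-3 was highest in the TGF-β G1 fraction (193 ± 15.6 TPM) and lowest in the KRTAP2-3 sgRNA clones (2.70 and 6.96 TPM).

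The first comparison asked what TGF-β changed in G1 cells. PMEPA1, a SMAD target that dampens TGF-β signalling, rose 29.2-fold, from 2.17 ± 0.101 to 99.8 ± 56.4 TPM (SD, n = 2; log2 4.87, SE 0.48). FN1, the matrix protein fibronectin, rose 25.3-fold (30.9 ± 18.5 to 749 ± 212 TPM), and TPM1, the actin-binding protein tropomyosin, rose 7.52-fold (60.1 ± 10.6 to 466 ± 141 TPM). PTGES, the prostaglandin E synthase, fell by 2.94 on the log2 scale, from 41.2 ± 5.37 to 4.51 ± 0.711 TPM (SE 0.20), and the epidermal differentiation factor ZNF750 fell by 2.51 (30.2 ± 2.59 to 4.48 ± 0.666 TPM). KRTAP2-3 rose 2.06-fold (93.1 ± 2.25 to 193 ± 15.6 TPM, log2 1.05, SE 0.12; limma adjusted p = 0.0328). Its copies KRTAP2-1, KRTAP2-2 and KRTAP2-4 had log2 differences of 1.34, 1.34 and 1.44 that passed with the replicate block (adjusted p = 0.00330, 0.00624 and 0.00381) and not without it (0.146, 0.124 and 0.132).

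Camera called 15 of the lists in G1, against 0 with an estimated correlation and 14 with fry. Those 14 included squamous differentiation, invasion proteases, and CDK inhibitors and D cyclins, which camera did not call. Fry did not call epithelial adhesion (fry adjusted p = 0.430), G1/S genes (0.742), interferon-stimulated genes (0.0521) or keratin-associated proteins (0.0673). Over all genes, limma called 101 of 13596 genes in G1, 63 higher and 38 lower, and 1036 higher and 424 lower with the replicate block. The share of higher calls depended on scaling: 40 of 96 calls were higher with trimmed-mean scaling, 36 of 76 with quantile normalization and 45 of 95 with FPKM. Trimmed-mean scaling moved the median of all genes from 0.10 to −0.00 for TGF-β in G1 and from 0.16 to 0.01 for the interaction, so list medians called relative are given minus the median of all genes, and the others as measured. Leaving out 1 library lowered the count to 2 (either unstimulated G1 library), 21 and 23 (unstimulated S/G2/M replicates 1 and 2), 16 and 0 (TGF-β G1 replicates 1 and 2) or 21 (either TGF-β S/G2/M library). The call of KRTAP2-3 ended in each case, with adjusted p of 0.160 and 0.162 (unstimulated G1 replicates 1 and 2), 0.0803 and 0.0804 (unstimulated S/G2/M), 0.108 and 0.156 (TGF-β G1), and 0.0700 and 0.0713 (TGF-β S/G2/M). It also ended with the spread of all 12 libraries (adjusted p = 0.120) and with that of the 2 compared groups (0.150), where 242 and 3 genes were called.

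The matrix and signalling genes that rose with TGF-β in G1 were spread over several lists. Of 24 measured TGF-β/SMAD targets, PMEPA1, TGM2, TGFBI and LTBP2 rose and the repressor TGIF1 fell (14 higher and 2 lower adjusted over the list alone, and 12 and 2 with the replicate block). TGM2, the crosslinking enzyme transglutaminase 2, went from 462 ± 3.95 to 1765 ± 76.7 TPM, and TGFBI, a secreted adhesion protein, from 1450 ± 371 to 6040 ± 249 TPM. The list median was 0.66 above that of all genes (camera adjusted p = 2.2e-06, and adjusted p = 0.212 with an estimated correlation). Of 37 collagens and matrix genes, 28 were higher in value and 5 rose, FN1, COL6A3, COL5A1, LAMA3 and LTBP2, while 17 rose and 6 fell with the replicate block (15 and 3 adjusted over the list alone). Their relative median was 0.43 (camera adjusted p = 3.9e-04, and adjusted p = 0.326 with an estimated correlation). Of 12 integrins, the adhesion receptor subunits ITGB5 (44.7 ± 14.3 to 157 ± 30.3 TPM) and ITGA2 (18.0 ± 3.17 to 62.4 ± 7.40 TPM) rose (4 and 0 adjusted over the list alone, 7 and 0 with the replicate block, relative median 0.36, camera adjusted p = 2.1e-04, and adjusted p = 0.310 with an estimated correlation). Of 15 mesenchymal markers and EMT factors, FN1 and CDH2 (N-cadherin, 6.08 ± 1.07 to 16.6 ± 2.03 TPM) rose (5 and 2 adjusted over the list alone, 7 and 0 with the replicate block, relative median 0.35, camera adjusted p = 0.0124, and adjusted p = 0.152 with an estimated correlation). VIM, encoding vimentin, had 149 ± 84.8 against 18.6 ± 12.3 TPM (adjusted p = 0.127, and 1.7e-04 with the replicate block). The EMT factor SNAI2 had 56.9 against 29.8 TPM (0.0621, and 0.0118 with the block). Of 23 invasion proteases and regulators MMP9, ADAM19 and ADAMTS6 rose and the urokinase receptor PLAUR fell (8 and 1 adjusted over the list alone, 8 and 4 with the replicate block); MMP9, a gelatinase, had 5.09 and 8.18 TPM against 0.417 and a listed 0. The mean of that list was 0.35 and its camera direction down (adjusted p = 0.976).

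ID genes, epithelial adhesion genes, interferon-stimulated genes, immediate early and heat shock genes and cytokines stood lower in G1 with TGF-β by camera. All 3 measured ID genes, SMAD-dependent inhibitors of differentiation, were lower (3 adjusted over the list alone, 0 over all genes and 3 with the replicate block; ID1 331 ± 153 against 833 ± 43.2 TPM, limma adjusted p = 0.163, and 0.0234 with the block), with a relative median of −1.41 (camera adjusted p = 1.4e-05, and adjusted p = 0.135 with an estimated correlation). Of 30 epithelial adhesion and identity genes OVOL1, a repressor of EMT genes, fell (14.8 ± 1.72 to 5.01 ± 0.260 TPM, 0 and 3 adjusted over the list alone, 3 and 7 with the replicate block, relative median −0.23, camera adjusted p = 9.1e-04, and adjusted p = 0.418 with an estimated correlation). CDH1, encoding E-cadherin, had 74.7 against 99.9 TPM (adjusted p = 0.483, and 0.0278 with the replicate block). Of 25 interferon-stimulated genes IFIT3 fell and 3 were higher in value (0 and 4 adjusted over the list alone, 0 and 4 with the replicate block, relative median −0.55, camera adjusted p = 8.0e-09, and adjusted p = 0.146 with an estimated correlation). Of 21 immediate early and heat shock genes NR4A1 fell (54.2 ± 14.2 to 13.0 ± 2.76 TPM, 1 and 8 adjusted over the list alone, 1 and 9 with the replicate block, relative median −0.45, camera adjusted p = 8.0e-09, and adjusted p = 0.0877 with an estimated correlation). That list was set up to read sorting stress, which was not separated from an effect of TGF-β. No cytokine of 15 passed, while with the replicate block LIF rose and 6 fell, IL1B among them at an adjusted p of 0.0155 against 0.240 (1 and 3 adjusted over the list alone, relative median −0.61, camera adjusted p = 3.9e-04, and adjusted p = 0.136 with an estimated correlation). Among 11 squamous differentiation genes, CNFN and the alarmin S100A9 (213 ± 116 to 25.8 ± 1.96 TPM) fell and 6 were higher in value (1 rose and 3 fell with the replicate block). The median (0.02) and mean (−0.45) of that list differ in sign (camera adjusted p = 0.0640).

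Cell cycle and housekeeping lists also moved in G1. PLK1, the mitotic kinase, rose 2.65-fold (19.4 ± 0.379 to 53.3 ± 4.84 TPM), and 39 of 45 G2/M genes were higher in value (15 and 0 adjusted over the list alone, 17 and 0 with the replicate block), with a relative median of 0.37 (camera adjusted p = 7.0e-08, and adjusted p = 0.310 with an estimated correlation). No gene of the 40 in G1/S and DNA replication passed, and GINS1 fell with the replicate block (relative median −0.15, camera adjusted p = 0.00754, and adjusted p = 0.569 with an estimated correlation). Of 22 cholesterol synthesis genes 1 rose (12 and 0 adjusted over the list alone, 14 and 0 with the replicate block, relative median 0.37, camera adjusted p = 1.2e-06, and adjusted p = 0.0877 with an estimated correlation). All 42 ribosomal protein genes were lower in value and none passed, though RPL10 fell with the replicate block (relative median −0.31, camera adjusted p = 4.7e-08, and adjusted p = 0.0877 with an estimated correlation). Of 7 measured keratin-associated proteins 5 were higher in value and 1 rose, KRTAP2-3 (4 and 1 adjusted over the list alone, 4 and 0 with the replicate block, relative median 0.94, camera adjusted p = 0.0491, and adjusted p = 0.438 with an estimated correlation). Fibroblast markers had 4 of 10 measured and COL6A3, also a matrix gene, rose (2 with the replicate block, relative median 0.47, camera adjusted p = 0.0373; adjusted p = 0.0937 with the block and 0.214 with an estimated correlation). The growth factor GDF15 fell from 217 ± 34.1 to 81.5 ± 15.7 TPM among 21 p53 targets (2 rose and 3 fell with the replicate block, median −0.05, mean 0.03, camera adjusted p = 0.585). CCNB1 (log2 1.00, limma adjusted p = 0.138), MKI67 (0.64, 0.176) and the CDK inhibitor CDKN2B (0.69, 0.154) passed with the replicate block (0.0197, 0.0156 and 0.0429). CDKN1A (0.29, 0.608), MCM2 (−0.21, 0.789), SMAD7 (0.33, 0.429), CDT1 (−0.11, 0.831) and GMNN (0.30, 0.522) did not pass. The other lists were not called: keratins (adjusted p = 0.311), invasion proteases (0.976), CDK inhibitors and D cyclins (0.611), hypoxia (0.0805), unfolded protein response (0.918), YAP/TAZ targets (0.660) and blood and endothelium (0.0758; 0.0317 with the replicate block). Leaving out 1 library ended the calls of G1/S genes (unstimulated G1 replicate 2, adjusted p = 0.388; TGF-β G1 replicate 2, 0.132), mesenchymal markers (TGF-β G1 replicate 2, 0.0859) and fibroblast markers (unstimulated G1 replicate 1, 0.169; TGF-β G1 replicate 1, 0.0900). That of keratin-associated proteins ended without 6 of the libraries, at most 0.229 (TGF-β G1 replicate 2) and 0.178 (unstimulated G1 replicate 1).

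The second comparison asked what TGF-β changed in S/G2/M cells. PMEPA1 rose 24.5-fold (2.63 ± 0.679 to 94.2 ± 50.3 TPM, log2 4.62, SE 0.48), FN1 14.0-fold (43.2 ± 27.1 to 563 ± 100 TPM) and TPM1 8.25-fold (51.8 ± 0.174 to 441 ± 109 TPM). WNT5B, a Wnt ligand, rose 6.87-fold (8.48 ± 0.639 to 66.0 ± 22.5 TPM). PTGES and ZNF750 fell by 2.96 and 2.65 on the log2 scale. The early response gene FOS fell from 1012 ± 108 to 320 ± 45.5 TPM (log2 −1.66, SE 0.17), and ID2 fell from 35.0 ± 2.88 to 10.2 ± 2.71 TPM. FOS belongs to the list set up to read sorting stress, which was not separated from an effect of TGF-β. KRTAP2-3 had 107 ± 7.50 against 83.2 ± 0.0364 TPM and did not pass (log2 0.35, SE 0.12, limma adjusted p = 0.321). Its copies KRTAP2-1, KRTAP2-2 and KRTAP2-4 (log2 0.77, 0.74 and 0.69), VIM (2.65), CDH1 (−0.97) and CDT1 (−0.57) did not pass (adjusted p between 0.165 and 0.498). With the replicate block their adjusted p was 0.0175, 0.0396, 0.0326, 2.5e-04, 0.00262 and 0.0229.

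Camera called 12 lists in S/G2/M, against 0 with an estimated correlation and 8 with fry. The fry calls included CDK inhibitors and D cyclins, which camera did not call. Fry did not call TGF-β/SMAD targets (fry adjusted p = 0.0518), epithelial adhesion (0.122), G1/S genes (0.122), YAP/TAZ targets (0.0608) or collagens (0.403). Limma called 86 genes, 37 higher and 49 lower (442 and 697 with the replicate block). Of the calls, 28 were higher in both fractions where independent calls would give 0.17, and 21 lower in both where they would give 0.14. The comparisons share no library but are not independent. They come from 1 fit with the same spread per gene, and libraries with the same replicate number deviated together. The chance values are therefore too low by an unknown amount. Effects correlated at 0.56 (Spearman 0.45) across genes, which are not independent replicates. Of the lists, TGF-β/SMAD targets (4 of 24 rose, 9 and 3 with the replicate block, 8 and 2 adjusted over the list alone, relative median 0.55, camera adjusted p = 3.4e-05, and adjusted p = 0.265 with an estimated correlation) and mesenchymal markers (1 of 15 rose, FN1, 4 and 0 with the block, 3 and 0 adjusted over the list alone, 0.23, 9.0e-04, and adjusted p = 0.124 with an estimated correlation) stood higher. So did cholesterol synthesis (0 of 22, 10 with the replicate block, 6 and 0 adjusted over the list alone, 0.49, 8.3e-10, and adjusted p = 0.0877 with an estimated correlation) and fibroblast markers (COL6A3 of 4 measured, 0.70, 0.00313, and adjusted p = 0.124 with an estimated correlation). Immediate early and heat shock genes stood lower, with FOS, NR4A1, EGR3 and DUSP1 of 21 fallen (12 with the replicate block, 13 adjusted over the list alone, relative median −0.62, camera adjusted p = 9.9e-11, and adjusted p = 0.0877 with an estimated correlation). Camera also called ID genes (relative median −1.36, adjusted p = 1.2e-04, and adjusted p = 0.124 with an estimated correlation), interferon-stimulated genes (−0.39, 9.7e-06, 0.250), cytokines (−0.51, 2.6e-04, 0.124), epithelial adhesion (−0.34, 2.6e-04, 0.404), G1/S genes (−0.21, 3.0e-05, 0.404) and YAP/TAZ targets (−0.19, 0.00840, 0.305), the last value of each being the adjusted p with an estimated correlation. Adjusted over the list alone, 3 ID genes, 5 interferon-stimulated genes and 7 cytokines were lower. With the replicate block 3 ID genes, 8 interferon-stimulated genes, 7 cytokines, 13 epithelial adhesion genes, 4 G1/S genes and 5 YAP/TAZ targets fell, and of these lists only epithelial adhesion had a gene that rose (1). Collagens and matrix genes (3 of 37 rose, 9 and 8 with the replicate block, median 0.01, camera adjusted p = 0.0452, and adjusted p = 0.571 with an estimated correlation and 0.173 with the replicate block) were less stable. They lost the call without either unstimulated G1 library (0.0574 and 0.0572 for replicates 1 and 2). Their median turned to −0.11 without unstimulated S/G2/M replicate 2 (0.423) and to −0.03 without TGF-β S/G2/M replicate 1 (0.0316). Keratins (0.0569) and ribosomal proteins (0.115) passed with the replicate block (adjusted p = 0.00400 and 0.0425). G2/M genes had a median of −0.18 (adjusted p = 0.140). Without 1 library the count was 5 (either unstimulated G1 library), 1 and 0 (unstimulated S/G2/M replicates 1 and 2), 21 and 20 (TGF-β G1), or 6 and 0 (TGF-β S/G2/M). With no filter it was 7, and with the spread of the 2 compared groups 0, where 1610 genes had an unadjusted p under 0.05 in the fit of 8 libraries.

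**Figure D2:**
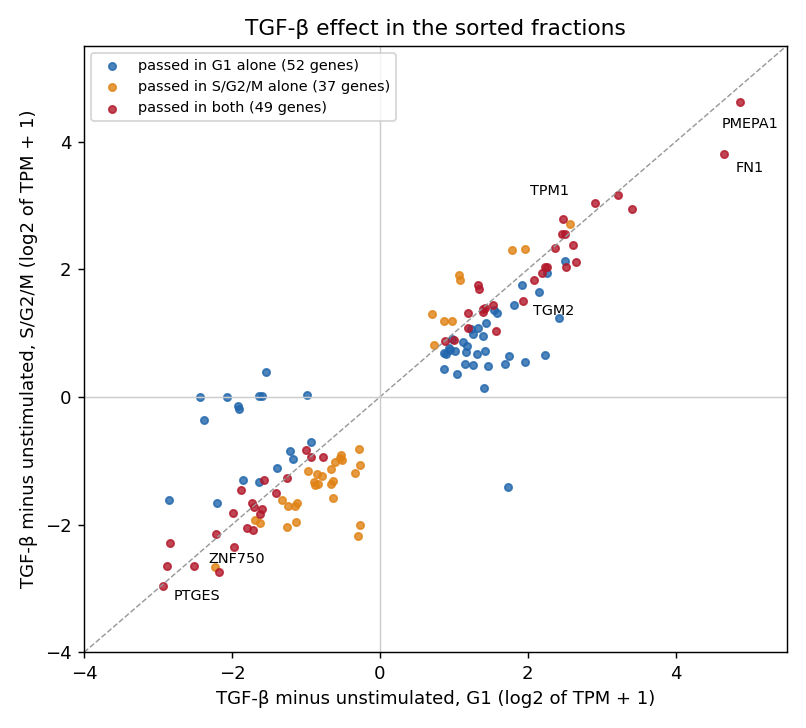
TGF-β effect (log2 of TPM + 1, TGF-β minus unstimulated) in G1 on the horizontal axis and in S/G2/M on the vertical axis; each point is a gene called in at least 1 fraction and the dashed line marks equal effects. Of these genes 49 passed in both fractions, 52 in G1 alone and 37 in S/G2/M alone.

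Whether the TGF-β effect differed between the fractions was tested as an interaction. Limma called 0 of 13596 genes (0 with the replicate block), with 645 at an unadjusted p under 0.05 and a smallest adjusted p of 0.718. KRTAP2-3 had an interaction of 0.69 (SE 0.17, adjusted p = 0.938), the proliferation marker MKI67 0.87 (SE 0.25, adjusted p = 0.938) and CCNB1, encoding cyclin B1, 0.79 (adjusted p = 0.938). The genes with the smallest p, LOC101927104, SLX1B-SULT1A4 and KRT83 among them, did not pass. Camera called 7 lists for the interaction, against 0 with an estimated correlation and 0 with fry. Without 1 library at most 1 gene passed (unstimulated G1 replicate 1, unstimulated S/G2/M replicate 2 or TGF-β S/G2/M replicate 1).

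The phase difference in unstimulated cells served to read the sort. PLK1 fell by 4.14 on the log2 scale in G1 against S/G2/M (19.4 ± 0.379 against 360 ± 56.9 TPM; SE 0.16, adjusted p = 2.5e-04), and TOP2A, the mitotic topoisomerase, by 4.07 (14.8 ± 0.589 against 272 ± 81.1 TPM). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, had 40.5 ± 5.52 against 557 ± 44.9 TPM and CCNB1 41.3 ± 9.65 against 377 ± 20.0 TPM. CCNE1, encoding the G1/S cyclin E1, rose 4.15-fold (24.9 ± 1.28 against 5.27 ± 0.844 TPM), as did the base excision enzyme UNG at 3.15-fold (211 ± 6.36 against 66.2 ± 2.66 TPM) and the replication factor MCM6 at 2.78-fold (104 ± 6.85 against 36.9 ± 4.23 TPM). CDT1 and GMNN, whose fragments the Fucci reporters carry so that reads may come from the reporters, had 177 ± 20.9 against 167 ± 1.55 and 680 ± 151 against 694 ± 60.5 TPM (adjusted p = 0.875 and 0.945). KRTAP2-3 differed by 0.16 on the log2 scale (adjusted p = 0.595). MCM2 (log2 0.54, adjusted p = 0.387), CDH1 (−0.38, 0.505) and SMAD7 (−0.60, 0.160) passed with the replicate block (0.0245, 0.0339 and 0.0418).

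Camera called 6 lists between the unstimulated phases, against 0 with an estimated correlation and 3 with fry. Those of fry were G2/M genes, squamous differentiation, and CDK inhibitors and D cyclins, the last not called by camera. Limma called 260 genes, 21 higher in G1 and 239 lower (301 and 1434 with the replicate block). Of 45 G2/M genes 44 fell, all but PTTG1 (45 adjusted over the list alone, relative median −2.93, camera adjusted p = 1.6e-72, and adjusted p = 0.119 with an estimated correlation). Of 40 G1/S genes CCNE1, E2F1, CCNE2 and MCM6 rose and RRM2 fell (10 and 3 adjusted over the list alone, 10 and 3 with the replicate block, relative median 0.27, camera adjusted p = 6.6e-04, and adjusted p = 0.547 with an estimated correlation). Keratins (13 of 13 higher in value, none passed, KRT15, KRT16 and KRT19 with the replicate block, relative median 0.36, adjusted p = 0.00110), squamous differentiation (CNFN rose, 3 with the block, 0.58, 0.00156) and ribosomal proteins (40 of 42 higher in value, none passed, 0.29, 2.7e-06) stood higher in G1 and YAP/TAZ targets lower (7 fell with the block, −0.21, 0.0118). With an estimated correlation their adjusted p was 0.545, 0.157, 0.157 and 0.545. Integrins (adjusted p = 0.0951) and immediate early genes (0.0572) passed with the replicate block (0.0246 and 0.0242). The count fell to 122 and 143 without unstimulated G1 replicates 1 and 2 and to 111 and 137 without unstimulated S/G2/M replicates 1 and 2.

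The phases were then compared within TGF-β-treated cells. TOP2A fell by 3.90 on the log2 scale in G1 (13.4 ± 1.80 against 214 ± 38.3 TPM), and UBE2C fell by 3.85 (38.8 ± 1.99 against 573 ± 7.66 TPM). CDK1, the mitotic kinase, fell by 3.08 (21.7 ± 1.33 against 190 ± 15.6 TPM). CCNE1 rose 3.91-fold (29.7 ± 4.97 against 6.86 ± 1.42 TPM) and CDCA7, a cell division regulator, 3.94-fold (33.8 ± 2.07 against 7.84 ± 0.761 TPM). KRTAP2-3 rose 1.80-fold in G1 (193 ± 15.6 against 107 ± 7.50 TPM; log2 0.85, SE 0.12, limma adjusted p = 0.0259); without TGF-β its difference was 0.16 (adjusted p = 0.595), and the interaction that tests the change did not pass (adjusted p = 0.938). GMNN had 825 ± 53.5 against 507 ± 14.8 TPM (adjusted p = 0.210). KRTAP2-1 (log2 0.78, adjusted p = 0.480), KRTAP2-4 (0.80, 0.478), MCM2 (0.75, 0.379) and CDT1 (0.55, 0.293) passed with the replicate block (0.0247, 0.0310, 0.0140 and 0.0371).

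Camera called 7 lists between the TGF-β phases, against 0 with an estimated correlation and 2 with fry. Those of fry were G2/M genes, and CDK inhibitors and D cyclins, the latter not called by camera. Limma called 178 genes, 26 higher and 152 lower (258 and 345 with the replicate block). Of the calls, 144 were lower in both phase comparisons (2.67 if calls were independent) and 8 higher in both (0.04 if independent), and the effects correlated at 0.57 across genes. Here too the shared fit and the replicate numbers make the calls dependent. G2/M genes fell in 42 of 45 cases (45 adjusted over the list alone, relative median −2.45, camera adjusted p = 6.7e-100, and adjusted p = 0.0655 with an estimated correlation), and 5 of 40 G1/S genes rose while RRM2 fell (17 and 1 adjusted over the list alone, 15 and 1 with the replicate block, relative median 0.31, camera adjusted p = 1.7e-05, and adjusted p = 0.486 with an estimated correlation). Keratins (relative median 0.55, camera adjusted p = 7.7e-06, and adjusted p = 0.450 with an estimated correlation), keratin-associated proteins (0.75, 0.00404, 0.486), collagens (0.23, 0.00940, 0.550) and cytokines (0.32, 0.00940, 0.450) stood higher in G1 and the unfolded protein response lower (−0.22, 0.0202, 0.486). With the block 8 keratins, 3 keratin-associated proteins, 4 collagens and 2 cytokines rose and none of these lists had a gene that fell, while 1 unfolded protein response gene rose and 1 fell. Ribosomal proteins (camera adjusted p = 0.0848) passed with the replicate block (adjusted p = 0.0127). The count fell to 94 and 93 without TGF-β G1 replicates 1 and 2 and to 75 and 91 without TGF-β S/G2/M replicates 1 and 2. List calls ended for cytokines without TGF-β G1 replicate 1 (adjusted p = 0.060), keratin-associated proteins without TGF-β G1 replicate 2 (0.0726), and the unfolded protein response without TGF-β G1 replicate 1 (0.149) or TGF-β S/G2/M replicate 2 (0.148).

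**Figure D3:**
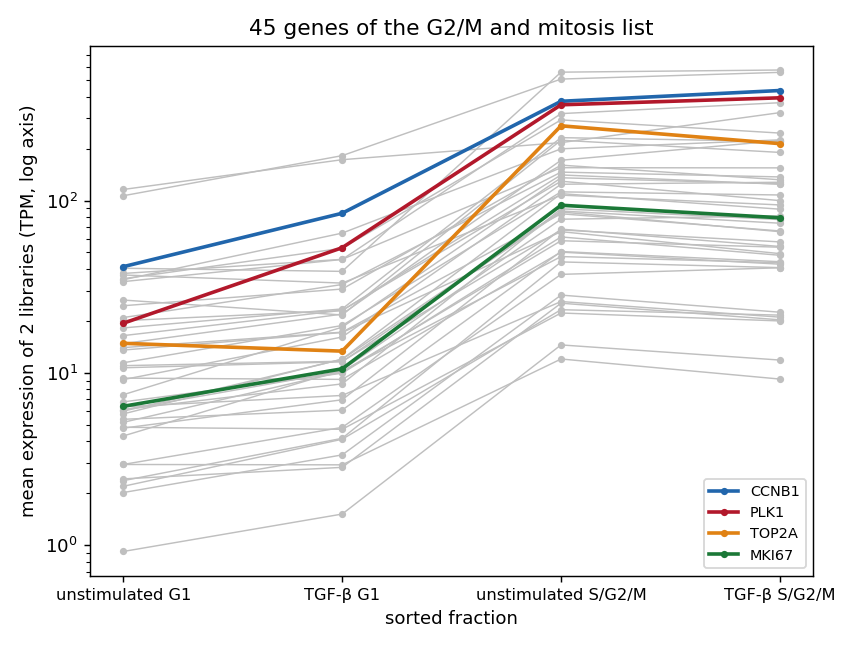
Mean expression (TPM of 2 libraries, log axis) of the 45 genes of the G2/M and mitosis list in the sorted fractions; each line is a gene. PLK1 ran from 19.4 TPM in unstimulated G1 and 53.3 TPM in TGF-β G1 to 360 TPM in unstimulated S/G2/M.

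The clone comparison asked what differed between cells with the KRTAP2-3 sgRNA and cells with the control sgRNA. S100A7, an antimicrobial protein of squamous epithelium, rose 8.07-fold (15.3 ± 0.538 to 131 ± 19.3 TPM, log2 3.01, SE 0.16), the basal keratin KRT15 4.67-fold (144 ± 58.2 to 657 ± 167 TPM) and IGFBP3, which binds insulin-like growth factors, 3.87-fold (398 ± 5.34 to 1548 ± 152 TPM). FN1 fell by 1.83 on the log2 scale (63.8 ± 21.9 to 16.7 ± 0.433 TPM), TGM2 by 1.52 (452 ± 44.1 to 157 ± 18.7 TPM) and the collagenase MMP1 by 2.05 (23.3 ± 5.59 to 4.81 ± 0.787 TPM). The simple-epithelium keratin KRT18 fell from 7010 ± 514 to 2554 ± 212 TPM and its partner KRT8 fell too, while KRT17 rose from 3309 ± 651 to 8148 ± 5.07 TPM. VIM was listed at 0 in both KRTAP2-3 sgRNA libraries against 12.6 and 15.6 TPM in the controls, and CDH2 at 0 against 7.13 and 4.74 TPM; S100A4 had 7.75 and 4.80 TPM against a listed 0 in both controls. MKI67 (log2 0.05, limma adjusted p = 0.958), CCNB1 (−0.32, 0.361), CDKN1A (0.15, 0.758), CDH1 (−0.51, 0.280) and SNAI2 (−0.10, 0.889) did not pass.

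Camera called 13 lists in the clones, against 0 with an estimated correlation and 0 with fry. Limma called 162 of 12993 genes, 65 higher and 97 lower. Of these, 36 were listed at 0 in a whole group and 27 overlapped another gene model. The count was 79 without control sgRNA replicate 1, 158 without control sgRNA replicate 2, 281 and 296 without KRTAP2-3 sgRNA replicates 1 and 2, and 1 with no filter on low values. Mesenchymal markers stood lower (4 of 14 fell and 1 rose, 1 and 8 adjusted over the list alone, median −0.75, camera adjusted p = 2.8e-06, and adjusted p = 0.439 with an estimated correlation). That list holds VIM, CDH2 and S100A4, each listed at 0 in a whole group, and no alternative left out all such genes. Invasion proteases stood lower as well (3 of 20 fell, MMP1 and TIMP1 among them, 0 and 7 adjusted over the list alone, −0.51, 3.1e-06, and adjusted p = 0.439 with an estimated correlation). TGF-β/SMAD targets (2 of 24 fell, TGM2 among them, 1 and 5 adjusted over the list alone, median −0.35, camera adjusted p = 6.5e-04, and adjusted p = 0.439 with an estimated correlation), cytokines (IL24 of 9, 0 and 2 adjusted over the list alone, −0.48, 9.0e-04, and adjusted p = 0.439 with an estimated correlation) and collagens (COL5A1 and FN1 of 37 fell, BGN rose, 4 and 10 adjusted over the list alone, −0.22, 0.00378, and adjusted p = 0.760 with an estimated correlation) stood lower too. ID genes (0 of 3, 2 and 0 adjusted over the list alone, median 0.83, camera adjusted p = 0.00682, and adjusted p = 0.439 with an estimated correlation), squamous differentiation (S100A7 and LCN2 of 12, 4 and 0 adjusted over the list alone, 0.24, 7.4e-04, and adjusted p = 0.517 with an estimated correlation) and the unfolded protein response (0.23, 0.00146, and adjusted p = 0.633 with an estimated correlation) stood higher.

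Camera also called 5 other lists in the clones in which no gene passed: G1/S (median −0.20, adjusted p = 0.00825, and adjusted p = 0.822 with an estimated correlation), G2/M (−0.18, 6.5e-04, 0.822), cholesterol synthesis (−0.19, 6.5e-04, 0.633), keratin-associated proteins (−0.64, 0.0441, 0.705) and ribosomal proteins (0.12, 0.0116, 0.822). Only 3 of 21 keratin-associated genes were measured, the sgRNA target KRTAP2-3 (log2 −1.94), its copy KRTAP2-4 (−0.64) and KRTAP4-1 (−0.03), so that call rests largely on the target. Without control sgRNA replicate 1 the medians of G1/S (0.03, adjusted p = 0.584), G2/M (0.04, 0.231) and ribosomal proteins (−0.06, 0.0200) changed sign. The calls of ID genes (0.226), squamous differentiation (0.0735) and keratin-associated proteins (0.129) ended as well. Without KRTAP2-3 sgRNA replicate 2 those of G1/S (0.714), G2/M (0.606), cholesterol synthesis (0.0532) and ribosomal proteins (0.0871) ended. The same held without KRTAP2-3 sgRNA replicate 1 for those of ribosomal (0.123) and keratin-associated proteins (0.104), and without control sgRNA replicate 2 for those of keratin-associated proteins (0.280) and the unfolded protein response (0.0517). Not called were epithelial adhesion (CLDN1 rose, CLDN4 fell, adjusted p = 0.101), keratins (2 rose, 3 fell, 0.0970), integrins (0.309, median 0.04, mean −0.14), CDK inhibitors (0.821, median 0.14, mean −0.07), p53 targets (0.943), interferon-stimulated genes (0.821), hypoxia (NDRG1 rose, 0.309), immediate early genes (EGR3 rose, 0.216), YAP/TAZ targets (0.269) and blood and endothelium (CD14 rose, 0.821, median −0.21, mean 0.11). Fibroblast markers had 2 measured members and were not tested.

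The genes that TGF-β moved in G1 were then read in the clones. Of the 63 that rose, 51 were measured in the clones, KRTAP2-3 among them, and 42 of these were lower with the KRTAP2-3 sgRNA (median −0.39, camera adjusted p = 4.0e-12). The adjusted p was 0.295 with an estimated correlation and 0.0827 with fry. The size of the median depended on the setting that defines the set. It was −0.12 with the replicate block and −0.90 without unstimulated S/G2/M replicate 1. FN1, TGM2, COL5A1, CDH2, HSD11B1, LAPTM5 and MCAM fell in the clones, 7 genes where chance gives 0.37 (Fisher's exact test, p = 7.8e-08). That test treats genes as independent and measures no spread between libraries. CDH2 had no signal listed in either KRTAP2-3 sgRNA library, which can be a failed estimate. Of the 38 that fell with TGF-β, 33 were measured (median −0.19, camera adjusted p = 0.0891). CD70, PTGES and TNFSF9 fell in the clones too (0.24 by chance) and TNNT3 rose. The direction of this set depended on the setting that defines it: its median was 0.037 with quantile normalization, 0.11 with trimmed-mean scaling, 0.10 with FPKM and 0.12 with the replicate block, where it passed as higher (camera adjusted p = 0.00783). The effects of TGF-β in G1 and of the KRTAP2-3 sgRNA correlated at −0.16 (Spearman −0.12) across 12755 genes, which are not independent replicates. HSD11B1, LAPTM5, MCAM, CD70, TNFSF9 and TNNT3 here, and TGIF1, CNFN, LIF, GINS1, RPL10, KRT15 between the phases, KRT16, KRT19, ADAMTS6, EGR3, DUSP1, RRM2 and PTTG1 above, complete short counts and were chosen after their values were seen.

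**Figure D4:**
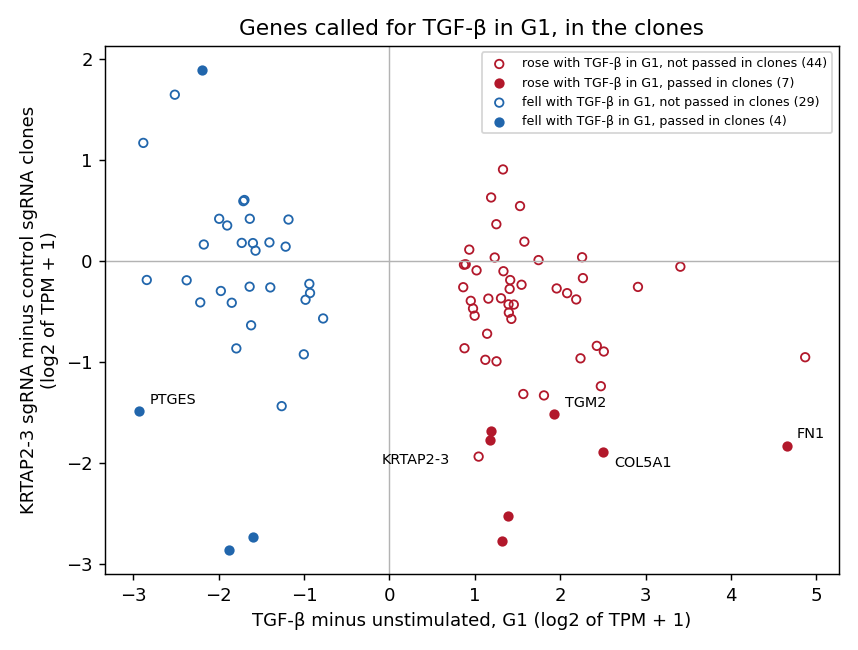
Genes called for TGF-β in G1, with the TGF-β effect on the horizontal axis and the difference between KRTAP2-3 sgRNA and control sgRNA clones on the vertical axis (both log2 of TPM + 1); filled points passed in the clones. Of 51 genes that rose with TGF-β, 42 lie below 0 in the clones.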

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

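Of the tests in this part, the scaling test of the G2/M genes was chosen after the result was seen.

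With TGF-β, 7 lists moved differently in G1 and in S/G2/M by limma's camera on the interaction. Their median interactions (TGF-β effect in G1 minus that in S/G2/M) were 0.64 for G2/M and mitosis (adjusted p = 7.6e-13), −0.28 for ribosomal proteins (1.2e-13), 0.44 for collagens and matrix (0.00592), 0.42 for integrins (0.00869), 0.41 for YAP/TAZ targets (6.7e-04), 0.33 for immediate early and heat shock genes (0.0481) and −0.034 for squamous differentiation (0.0481). Relative to the median of all genes they were 0.48, −0.44, 0.28, 0.26, 0.25, 0.17 and −0.19. With an estimated correlation the adjusted p was 0.497, 0.0762, 0.730, 0.730, 0.492, 0.696 and 0.492, and fry called none. Squamous differentiation lost the call with the replicate block (adjusted p = 0.104), and its measured median turned to 0.034 with all 12 libraries or without genes at 0 in 1 library, 0.16 without unstimulated G1 replicate 1, 0.026 without unstimulated S/G2/M replicate 2 and 0.053 without TGF-β G1 replicate 2. Limma called 0 single genes for the interaction, with or without the block, and 645 had an unadjusted p under 0.05. Leaving out 1 library ended the calls of collagens (unstimulated G1 replicate 2, 0.163; unstimulated S/G2/M replicate 1, 0.220) and integrins (unstimulated S/G2/M replicate 1, 0.220). Immediate early genes lost it without unstimulated G1 replicate 1 (0.419), unstimulated S/G2/M replicate 2 (0.407), TGF-β G1 replicates 1 and 2 (0.0635 and 0.0689) or TGF-β S/G2/M replicate 1 (0.233). Squamous differentiation lost it without each of the 7 sorted libraries other than unstimulated S/G2/M replicate 1 (0.0563 to 0.783).

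G2/M genes were higher with TGF-β in the G1 fraction, with a list median of 0.47, although 1 of 45 passed singly (17 rose and 0 fell with the replicate block) and the list call was lost with an estimated correlation (adjusted p = 0.310). With trimmed-mean scaling the median was 0.36, which argues against library scaling as the whole cause. A candidate explanation is that more S/G2/M cells were carried into the TGF-β G1 fraction: the list implied a carry-over of 5.12% in replicate 1 and 5.66% in replicate 2. Over 195 other genes called lower in unstimulated G1 than in S/G2/M, the change lay 0.07 above what that carry-over predicts (0.12 and 0.03). These genes were chosen by low values in the same unstimulated G1 libraries that the change is measured from. That choice tilts the change upward, so the comparison cannot decide. Of the 45 list genes 39 were higher in value, while TOP2A and UBE2C had lower mean TPM than in unstimulated G1. The 62 histone genes, also lower in unstimulated G1 than in S/G2/M (median −1.75), did not share the rise (median −0.08, 26 higher in value). The histone genes were picked after their values were seen. An effect of TGF-β on the G1 cells themselves stays open and was not tested.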

How the results depend on the processing

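Of the alternatives, 4 were chosen after seeing the data (gene IDs not summed, no small or mitochondrial RNA, no overlapping gene models, no genes listed at 0 in 1 library of a pair). The tally below covers the results reported here, a restriction made after a wider run. Most named genes and lists kept direction and side of the threshold with another pseudocount or scaling, and many did not elsewhere: with a pseudocount of 0.1, 270 did and 15 lost the call; with trimmed-mean scaling 260 did, 23 lost it and 2 reversed; with no filter 203 did, 80 lost it and 2 reversed; with the spread of the 2 compared groups, fewer libraries, 123 did and 72 lost it. Of 60 list calls 0 were kept with an estimated correlation and 21 with fry, and leaving out 1 sorted library lost 56 to 66 calls. Among those lost with an estimated correlation were G2/M genes between the unstimulated phases, of which 44 of 45 fell (camera adjusted p = 0.119). A loss in that setting therefore cannot decide about a list. The cause was not tested for any change below unless it is named, and depth was not set against any result, since the files used here list no read counts. Where an arm kept 1 library, that library was assumed to vary like the other groups.

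The replicate block gave 1460 genes for TGF-β in G1, 1139 in S/G2/M, 1735 between the phases without TGF-β and 603 with it. In the clones, whose labels do not say what the replicate number marks (correlation of deviations 0.14), it gave 753, with KRTAP2-3 at −1.94 (adjusted p = 1.5e-04). The sets of genes higher and lower with TGF-β in G1 are redefined by each setting. With the block their medians in the clones were −0.12 (adjusted p = 2.8e-07) and 0.12, where the lower set passed in the opposite direction (0.00783). Besides the calls given beside their results, CDH1 in the clones passed with the block (adjusted p = 0.0464). List calls that ended with the block were fibroblast markers for TGF-β in G1 (0.0937), collagens for TGF-β in S/G2/M (0.173) and squamous differentiation in the interaction (0.104). Lists called only with it were blood and endothelium markers for TGF-β in G1 (0.0317), epithelial keratins (0.00400) and ribosomal proteins (0.0425) for TGF-β in S/G2/M, integrins (0.0246) and immediate early genes (0.0242) between the phases without TGF-β, ribosomal proteins between the phases with it (0.0127), and epithelial keratins (0.0264) and keratin-associated proteins (0.0432) in the interaction.

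Counts moved by over 1.5 times in other settings. For TGF-β in G1 they were 47 with no filter, 242 with the spread of all 12 libraries and 3 with that of the 2 compared groups. For TGF-β in S/G2/M they were 7 with no filter, 131 with quantile normalization, 32 without the trend, 221 with all 12 libraries, 0 with the 2 compared groups and 146 without small and mitochondrial RNA. The 2 compared groups gave 141 and 110 for the phases without and with TGF-β. The clones had 85 with a pseudocount of 0.1, 1 with no filter, 86 with quantile normalization and 71 with trimmed-mean scaling. Leaving out 1 library gave 0 (TGF-β G1 replicate 2) to 23 genes for TGF-β in G1 and 0 (unstimulated or TGF-β S/G2/M replicate 2) to 21 in S/G2/M, and every library of the sorted cells lowered both counts by over 1.5 times. It gave 111 to 215 between the phases without TGF-β, 75 to 155 with it, 0 to 1 for the interaction, and in the clones 79 (without control replicate 1), 281 and 296 (without KRTAP2-3 sgRNA replicates 1 and 2). With an estimated correlation 0 lists were called in each of the 6 contrasts, and with fry 0 for the interaction, 0 in the clones, 3 between the phases without and 2 with TGF-β.

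KRTAP2-3 in G1 had 1.05 with the spread of all 12 libraries and with that of the 2 compared groups, where its call ended, and 0.96 to 1.13 with 1 library left out, where it ended for each of the 8 sorted libraries (adjusted p from 0.0700 to 0.162). In the clones KRTAP2-3 passed at −1.94 with a filter of 5 TPM, with all 12 libraries, without overlapping genes, without small RNA (−1.94) and without genes at 0 in 1 library, and at −1.37 with a pseudocount of 5. With a KRTAP2-3 sgRNA library left out, where that group keeps 1 library, the difference was −2.49 to −1.39. The genes higher with TGF-β in G1 (median −0.39 in the clones) lost the call with an estimated correlation and with fry, which leave the median as it is. With 1 library left out their median was −0.90 (either unstimulated S/G2/M library), −0.84 (TGF-β G1 replicate 1), −0.61 (either TGF-β S/G2/M library), −0.25 and −0.53 (control sgRNA replicates 1 and 2), and −0.41 and −0.38 (KRTAP2-3 sgRNA replicates 1 and 2). Where a sorted library was left out, the set itself held far fewer genes. The genes lower with TGF-β in G1 passed in the clones at −0.25 (pseudocount 0.1), −0.15 (pseudocount 5), −0.52 (no filter), −0.21 (no trend), −0.21 (no overlapping genes) and −0.19 (no genes at 0 in 1 library). Their median turned to 0.037 with quantile normalization, 0.11 with trimmed-mean scaling, 0.10 with FPKM, 0.051 with all 12 libraries and 0.11 without small RNA, and ran from −1.06 to 0.087 with 1 library left out. They passed without either unstimulated S/G2/M library (−1.06, adjusted p = 4.7e-05), either TGF-β S/G2/M library (−0.52, 0.0147), control sgRNA replicate 1 (−0.25, 1.4e-04) or KRTAP2-3 sgRNA replicate 2 (−0.29, 0.0138). Without either unstimulated G1 library or TGF-β G1 replicate 2 too few genes passed to form the sets, so no value is given.

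The median of keratin-associated proteins in G1 was 0.00 with no filter, where the call was lost (adjusted p = 0.901). List medians that turned were collagens in S/G2/M (−0.072 with no filter, −0.029 with all 12 libraries, −0.11 to 0.27 with 1 library left out), and squamous differentiation in the interaction (0.034 with all 12 libraries, 0.034 without genes at 0 in 1 library, −0.26 to 0.16 with 1 library left out). With 1 library left out, G1/S genes ran from −0.15 to 0.052 for TGF-β in G1 (highest without TGF-β G1 replicate 2) and from −0.31 to 0.035 in the clones, G2/M genes from −0.40 to 0.036 and ribosomal proteins from −0.058 to 0.28 in the clones. In the clones all 3 turned without control replicate 1.

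The single genes below passed neither with another scaling nor with 1 library left out. Under another scaling GMNN between the unstimulated phases turned to 0.065 (trimmed-mean) and 0.063 (FPKM), and CDKN2B between the TGF-β phases to −0.032 (quantile), −0.028 (trimmed-mean) and −0.0006 (FPKM). In the clones CDT1 turned to 0.027 and MCM2 to 0.0014 with quantile normalization. With 1 library left out, the clone differences ran from −0.0068 to 0.30 (CDKN1A), −0.076 to 0.035 (CDT1), −0.27 to 0.11 (GMNN), −0.29 to 0.14 (MCM2), −0.24 to 0.34 (MKI67) and −0.20 to 0.0096 (SNAI2). For TGF-β in G1 they ran from −0.010 to 0.58 (CDKN1A) and −0.23 to 0.012 (CDT1), in S/G2/M from −0.011 to 0.22 (CDKN1A), and for the interaction from −0.11 to 0.48 (CDKN1A), −0.12 to 0.54 (MCM2) and −0.36 to 1.02 (VIM). Between the unstimulated phases they ran from −0.052 to 0.54 (CDKN1A), −0.039 to 0.20 (CDT1), −1.12 to 0.22 (FN1), −0.27 to 0.18 (GMNN), −0.12 to 0.54 (KRTAP2-1), −0.26 to 0.55 (KRTAP2-2), −0.28 to 0.39 (KRTAP2-4) and −0.94 to 0.44 (VIM). Between the TGF-β phases they ran from −0.085 to 0.41 (CDH1), −0.072 to 0.11 (CDKN2B), −0.27 to 0.036 (SMAD7), −0.064 to 0.26 (SNAI2) and −0.53 to 0.69 (VIM).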

Other observations

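The reading of the genes regulated by TGF-β in the clones was planned, and the tests of its explanations, like that of the ratio between the KRTAP2 copies and KRTAP2-3, were chosen after the results were seen.

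Histone genes, which are transcribed in S phase to package new DNA, followed the sort. Of 62 measured genes with HIST names, 22 fell in G1 against S/G2/M without TGF-β (median −1.75) and 18 fell with TGF-β (median −1.53), and none rose in either. HIST1H4H had 0.532 ± 0.392 against 13.2 ± 6.01 TPM (SD, n = 2) between the TGF-β phases. The libraries were made from polyadenylated RNA and many histone transcripts lack a poly(A) tail, so these levels hold only for the transcripts captured. Between TGF-β and unstimulated cells their median was −0.08 in G1 and −0.24 in S/G2/M. Both groups of genes in this part were picked after their values were seen.

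Chorionic gonadotropin beta genes, placental hormone genes on chromosome 19, were higher with TGF-β. All 6 measured genes with CGB names were higher in value in G1 (median log2 difference 2.69, 1 past the threshold) and in S/G2/M (2.81, 2 past it). CGB8 (chromosome 19, 49047638 to 49049111) rose from 0.645 ± 0.175 to 14.8 ± 5.35 TPM (SD, n = 2) in G1. These genes are near-identical copies, so their separate values are uncertain.

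Genes that rose with TGF-β in G1 were lower in the KRTAP2-3 sgRNA clones, with a median of −0.39 over 51 genes (−0.25 without control replicate 1, and −0.12 over the larger set that the replicate block defines, both past the threshold), and the call was lost with an estimated correlation (adjusted p = 0.295) and with fry (0.0827). Library scaling moves all genes alike, and the set's median lay −0.41 from that of all genes (SE of the set's mean 0.11), which argues against it. Genes near the floor are argued against too, since the 32 members with at least 10 TPM had a median of −0.34, 26 of them lower. A difference between clones that does not come from the KRTAP2-3 sgRNA could account for it and stays open: the control replicates differed by a median of 0.30 over the set (the KRTAP2-3 sgRNA replicates by −0.03). An effect of KRTAP2-3 loss on these genes stays open too, as a hypothesis from 2 libraries per group.

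KRTAP2-1, KRTAP2-2 and KRTAP2-4 were higher with TGF-β beside KRTAP2-3. A constant share of KRTAP2-3 reads assigned to the copies would leave their ratio to KRTAP2-3 unchanged. With TGF-β it moved by a mean log2 of 0.47 (SE 0.05, 0.34 to 0.59 over 4 pairs of libraries). The ratio also differed between replicates of 1 group, at 0.156 and 0.265 in unstimulated G1 and 0.235 and 0.337 in TGF-β G1. The share need not be constant between libraries, so the shift cannot decide whether such reads are the whole cause. Reads too alike to be told apart may account for part or all of it. Words of 50 bases that also occur in KRTAP2-3 made up 35.5% of those in KRTAP2-1, 36.4% in KRTAP2-2 and 45.6% in KRTAP2-4 (22.4% of the 1465 different words in the 3 together). The read length is not given in the sources used here. A response of the copies themselves stays open.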
